A study of Crocosphaera watsonii WH 8501 with 36 samples.

How the data were processed

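RNA sequencing was carried out on cultures of the unicellular nitrogen-fixing cyanobacterium Crocosphaera watsonii WH8501. The labels describe 36 libraries in 12 groups of 3. In all, 2 tables of the whole series were deposited by the authors. One holds whole-number read counts per feature as deposited, and the other holds normalized values, going by its name. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts, Subread 2.0.1 and DESeq2 1.28.0, without their roles. The genome build is not given in the sources used here.

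Each table has 36 columns of per-sample values. None of the column names occurs in the labels of any sample, so 0 of 36 columns were matched to a sample or a group. Matching them by their order was not done, since the order of columns is not evidence of what a column holds. All 36 columns were therefore left unused, and no level, fold change or test was computed from either table. The features carry numeric identifiers without gene names, and no annotation was used here, so the gene lists fixed before the data were examined were not applied.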

Results

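Cultures of Crocosphaera watsonii WH8501, a unicellular marine cyanobacterium that fixes nitrogen, were kept under 3 combinations of temperature and acidity. The coolest cultures, at 26 °C, had a target pH of 8.1. The target pH was 8.0 for those at 28 °C and 7.9 for the warmest, at 30 °C. At time label 2 the recorded pH was 8.034 at 26 °C, 7.999 at 28 °C and 7.892 at 30 °C. At time label 4 the recorded pH was 8.141 at 26 °C, 7.979 at 28 °C and 7.881 at 30 °C. The labels give no unit for the time. Bottles either received dissolved organic matter (DOM) to a final concentration of 20 µM carbon or were left unamended. The recorded pH is the same for both kinds of bottle and for all replicates at a given temperature and time. No pH is given for single bottles. Each combination of temperature and acidity, DOM and time was represented by 3 libraries, which gave 12 groups and 36 libraries. Temperature and pH were changed together, so the design has no contrast that would tell them apart. The 26 °C condition came from 2 tanks and the other conditions from 3 tanks each. The labels do not say which tank a bottle came from. With 2 tanks for 3 libraries, each 26 °C group must include libraries that share a tank. At 28 °C and 30 °C, the 3 libraries of a group cannot be taken as coming from separate tanks.

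The design implies a comparison of DOM-amended with unamended bottles under each condition and time, a comparison of the warmer and more acidic conditions with 26 °C, and a comparison of the time labels. None of these comparisons was made. The 36 columns of the count table and of the normalized table carry names that occur in no sample's labels, so no column could be assigned to a condition. No expression level, fold change or p-value is reported for any gene.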

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

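The number of table columns matched to a sample was 0 of 36 when the whole column name was looked up in the labels. It was also 0 when the digits of the name alone were looked up as a whole number. The number was again 0 when the name was searched for anywhere in the label text, parts of words included. That search covers the whole-name rule, so the 2 zeros are not separate results. Both the digit rule and the search of the label text were chosen after seeing the data. No paired analysis was possible because the columns of the tables carry no replicate letter and were matched to no sample. The labels also do not say whether the same bottles were sampled at both time labels, so the replicate letters are not a known pairing. The settings chosen before the data were examined (another test, normalization, filter or set of libraries) were not run, since no comparison was made.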
